A study of Homo sapiens with 10 samples.

How the data were processed

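Total RNA of cardiomyocytes derived from H1 human embryonic stem cells was sequenced in 10 libraries, 5 transfected with a control GapmeR and 5 with a GapmeR against CLIPPER. Groups and replicate numbers came from the sample titles. The deposited table holds raw counts of reads per gene, whole numbers for 78932 gene identifiers, not normalised. Its control columns spell the control abbreviation differently from the labels and were matched through the full titles; 0 columns of samples were left unmapped. Per the labels, ribosomal RNA was removed and strand-specific libraries were made. Per the submitters' processing notes and the design text, the authors trimmed the reads with Trim Galore 0.65, aligned them to GRCh38 with STAR 2.7.0 using GENCODE release 38 and counted them with HTSeq. The HTSeq version and its strand setting are not given in the sources used here. The further scaling to CPM and to gene length that the design text mentions was not applied to this table.

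Gene names, positions, spans and classes were taken by identifier from GENCODE release 44, on the same assembly. Of the 78932 identifiers 61481 matched. The other 17451, which held 0.25% to 0.408% of the counts of a library, were kept in library sizes and tests without a name, and 1060 of them were tested. Gene span is the length from the start to the end of the annotated gene, introns included. No gene in these tables is named CLIPPER, and the target RNA was not analysed here.

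Library totals were 32.9 to 45.1 in units of 1e6 counts. No 2 libraries agreed within sampling noise (lowest chi-square per degree of freedom 4.13), so all 10 were used. Counts were normalised with the trimmed mean of M-values and tested with the quasi-likelihood F test of edgeR 4.0.16 (filterByExpr, robust dispersions, Benjamini-Hochberg adjustment over 21033 genes, threshold 0.05), in R 4.3.3. Standard errors are the log2 fold change divided by the square root of F. The common biological coefficient of variation was 19.2%. The normalisation assumes that rises and falls of most genes balance, which a table with 79.7% of genes changed cannot check, so fold changes are relative to the bulk of genes and not to RNA per cell. Nothing in the labels says that the replicates came from separate cultures or differentiations. The p-values then measure the spread between these samples only, which may be technical. Single shares were compared with exact permutation tests over all 252 labelings, whose smallest two-sided p is 0.00794.

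Gene lists (48, of which 47 had at least 5 tested members) were fixed before the data were examined and tested with camera of limma 3.58.1 with a preset correlation of 0.01. Alternatives were an estimated correlation and fry. Member counts cover tested genes only. These were 7 of 14 listed pluripotency markers, 5 of 18 endoderm markers, 15 of 28 replication-dependent histone genes and 23 of 34 interferon-induced genes. Named genes followed a rule also fixed before the data were examined: LPIN1 and the tested genes within 1 Mb of it, and the 10 largest rises and 10 largest falls among genes with an adjusted p below 0.05, a mean of at least 1 CPM, a gene symbol and no overlap between the groups. To these came the 5 rises and 5 falls with the smallest p under the same conditions, the 3 falling genes of any class with the smallest p, and for each list up to 2 rising and 2 falling members with the smallest p. Some genes that the rule takes are not reported here. PPARGC1A, MYH6, MYH7 and MKI67 were added after their values were seen. Counts and floors cover counting error only.

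Other settings tried were DESeq2's size factors, upper-quartile factors, DESeq2 1.42.0, limma-voom, no filter beyond 1 count, a mean of at least 1 CPM, no robust dispersion, mitochondrial genome genes removed, the replicate number as a block, and each library left out in turn. Chosen after seeing the data were leaving out knockdown replicates 1 and 2 together, list tests after removing a loess trend (span 0.5) on gene span with the preset and with estimated correlations, the span of the canonical transcript, and the percentile among the 500 coding genes nearest in span. The gene test was tested on simulated data with the means, library sizes and dispersions of these libraries for the knockdown against control comparison. Over 20626 tested genes it recovered 38.8% of 67 genes changed 1.5-fold, 82.1% of 67 changed 2-fold and 100% of 66 changed 4-fold, with 4 false calls among 151 (2.65%). The changed genes were drawn from those with a mean of at least 1 CPM, so recovery below that level was not measured. No other gene was changed in the simulation. It therefore does not measure the false calls in data where 79.7% of genes changed. Figures were drawn with matplotlib 3.10.9.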

Results

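RNA was measured in cardiomyocytes derived from H1, an established human embryonic stem cell line, after transfection with a GapmeR, an antisense oligonucleotide that pairs with an RNA and directs RNase H to cut it. Beating cells received 50 nM of a control GapmeR or of a GapmeR against the RNA named CLIPPER on day 9 of differentiation and were collected 48 hours later. There were 5 control and 5 knockdown libraries of total RNA. Gene counts per library, in units of 1e6, were 32.9 to 45.1, so that 1 count in a library of average size stood for about 0.026 CPM (counts scaled to a library total of 1e6). On average 32215 ± 417 genes (SD, n = 5) had counts in a control library and 32838 ± 688 (SD, n = 5) in a knockdown library (exact permutation test, two-sided p = 0.127). No gene in the annotation used here carries the name CLIPPER, so the level of the targeted RNA was not analysed here and the labels were not checked against it.

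The first principal component of the log2 CPM values held 85.2% of the variance and separated all knockdown from all control libraries. Rank correlations between libraries were 0.989 to 0.994 within the control group, 0.962 to 0.994 within the knockdown group and 0.849 to 0.934 between the groups. Knockdown replicate 2 lay nearest to the controls on the first component (-49.5), followed by replicate 1 (-93.3). Genes of the mitochondrial genome took 11.3% ± 0.865 of the counts in control and 14.4% ± 2.99 in knockdown libraries (SD, n = 5, exact permutation test, two-sided p = 0.0952). The share of long non-coding RNA genes was 1.83% ± 0.0736 in control and 2.89% ± 0.121 in knockdown libraries (SD, n = 5). That difference had the smallest p such a test can give here (exact permutation, two-sided p = 0.00794, adjusted p = 0.0132 over 5 shares).

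The title of the series asks whether CLIPPER acts on mitochondrial biogenesis through LPIN1, the phosphatidate phosphatase lipin 1, which makes diacylglycerol and also acts as a transcriptional coactivator of fatty acid oxidation genes. LPIN1 (ENSG00000134324, chromosome 2, 11677595 to 11827409 on the plus strand, GRCh38) was 2.15-fold lower in the knockdown group. Its level was 118 ± 5.57 CPM in control and 55.2 ± 8.56 CPM in knockdown libraries (SD, n = 5). The log2 fold change was -1.10 ± 0.106 (SE), with an adjusted p of 1.4e-06 in edgeR's quasi-likelihood test, and all 5 knockdown libraries lay below all 5 controls. LPIN1 spans 150 kb, and the 500 protein-coding genes nearest to it in span had a median log2 fold change of -1.24. LPIN1 stood at the 55.6th percentile of these genes.

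**Figure D1:**
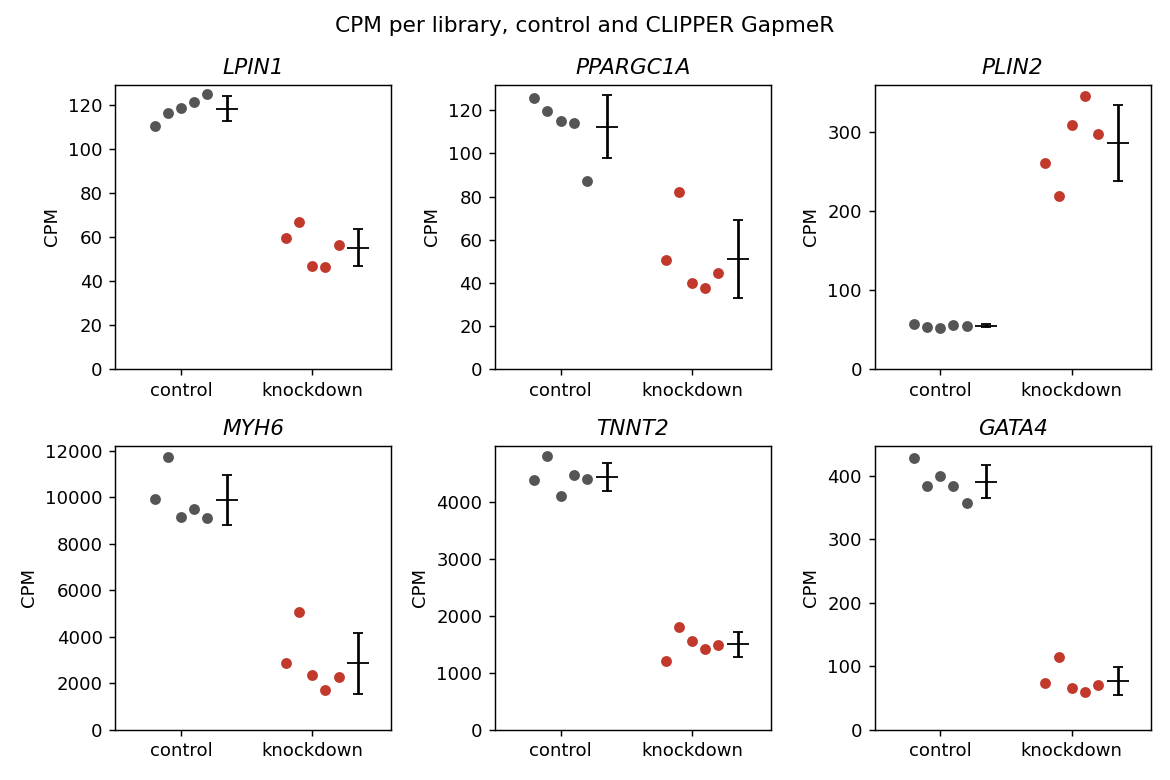
CPM per library of LPIN1, PPARGC1A, PLIN2, MYH6, TNNT2 and GATA4 in control (grey) and knockdown (red) libraries, in the order of replicates 1 to 5, with the mean and SD beside them. LPIN1 fell from 118 to 55.2 CPM and PLIN2 rose from 54.7 to 287 CPM, with no overlap between the groups.

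Other genes within 1 Mb of LPIN1 moved both ways. GREB1, an estrogen-responsive gene 34.8 kb upstream, had a log2 fold change of -2.58 ± 0.245 (SE), which was 5.96-fold lower. The kinase gene ROCK2, NOL10 and PDIA6 fell, with log2 fold changes of -0.94, -0.31 and -0.32. KCNF1 rose by 1.81 ± 0.248, C2orf50 by 1.24 ± 0.306 and RN7SL832P by 3.26 ± 0.276, from 0.809, 0.288 and 0.142 CPM in control libraries. TRIB2 (log2 fold change -0.12), E2F6 (0.20), SLC66A3 (-0.13), ATP6V1C2 (0.11), LINC01954 (0.30), ENSG00000286427 (-0.74) and ENSG00000225649 (-0.49) did not pass the test. With upper-quartile scaling NOL10 and PDIA6 did not pass (log2 fold changes -0.11 and -0.12) and E2F6 did (0.39). TRIB2 passed without knockdown replicate 2 (-0.19) and E2F6 without knockdown replicate 5 (0.25). The long non-coding genes inside the span of LPIN1 had too few counts to be tested, the most abundant being ENSG00000228496 with 31 counts over all 10 libraries.

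Across the transcriptome, 16773 of 21033 tested genes (79.7%) differed between the groups at an adjusted p below 0.05, 8441 higher and 8332 lower in the knockdown. The change was at least 2-fold for 5115 of the higher and 5099 of the lower genes. In 14195 genes (67.5%) the groups did not overlap, against 0.794% by chance. The median log2 fold change of all tested genes was 0.0056, and upper-quartile scaling shifted all genes by 0.20, so changes are relative to the bulk of genes.

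Most of the genes with the largest rises had very few counts in control libraries, apart from DDN and TMEM151B with 589 and 179 counts in all. TH, which encodes the rate-limiting enzyme of catecholamine synthesis, went from 0.011 ± 0.0152 to 7.68 ± 1.96 CPM (SD, n = 5), with 2 counts in all control and 1514 in all knockdown libraries. After scaling by normalised library sizes the ratio of these counts was 751, with a 95% counting interval from 207 to 6205. For LCNL1 (3 and 570 counts) the ratio scaled likewise was 188, with an interval from 64.1 to 916, and for the cytokine gene TNF (2 and 356 counts) it was 177, with an interval from 48.5 to 1463. The histamine receptor gene HRH3 rose by 7.16 ± 0.676 (SE) on the log2 scale, TMEM151B by 6.40 ± 0.396, the immune checkpoint receptor gene PDCD1 by 6.24 ± 0.428, and DDN by 6.21 ± 0.314. CDCA4P4 rose by 6.10, RANBP3-DT by 5.88 and FOXJ1, the regulator of motile cilia, by 5.79. DDN reached 225 ± 87.7 CPM from 3.03 ± 0.573, and TMEM151B 78.8 ± 37.2 CPM from 0.923 ± 0.234. Single libraries moved some of these folds, on the linear scale, by over 1.5 times. The log2 fold change of TNF was 7.22, and 6.63 without knockdown replicate 4, and that of HRH3 was 7.84 without control replicate 2, PDCD1 7.04 and RANBP3-DT 6.50 without control replicate 4, and FOXJ1 6.38 without control replicate 1. The counts of LCNL1, TMEM151B, CDCA4P4 and RANBP3-DT are uncertain because these genes overlap a coding gene.

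The largest falls included the ion channel genes KCNE2 and CACNA1D among genes of other kinds. The log2 fold change was -3.81 ± 0.229 (SE) for CPNE4, -3.80 ± 0.348 for NSG2, -3.62 ± 0.313 for KCNE2, an accessory potassium channel subunit, and -3.54 ± 0.359 for CCSER1. CACNA1D, the L-type calcium channel of pacemaker cells, fell from 50.4 ± 10.8 to 4.52 ± 1.12 CPM (SD, n = 5), which was 11.1-fold. It was -3.63 for FAM238C and -3.40 for SLC5A4-AS1 (-4.22 without knockdown replicate 2). The values of DMRTC1, -5.85 (-7.00 without knockdown replicate 5), and of the read-through locus ATP5MF-PTCD1, -4.63 (-6.78 without knockdown replicate 2), are uncertain, as both overlap other coding genes. Judged by the smallest p, the clearest rises were RASD1 (8.16-fold, from 8.21 ± 0.87 to 67.0 ± 1.66 CPM), KMT2E-AS1 (log2 fold change 3.46), STAC3 (27.5-fold), the small nucleolar RNA host gene SNHG4 (14.5-fold) and GOT1-DT (5.64-fold). The clearest falls by that measure were NBEAL1 (4.33-fold, from 52.5 ± 2.63 to 12.1 ± 1.16 CPM), the myosin gene MYO1D (4.55-fold), the receptor phosphatase gene PTPRG (7.27-fold), SLC4A5 (5.86-fold) and BMERB1 (4.04-fold). Adjusted p-values of these 10 genes lay between 4.2e-09 and 1.3e-08 in edgeR's quasi-likelihood test. Overlap with another coding gene makes the counts of CACNA1D, SLC5A4-AS1, KMT2E-AS1, STAC3, SNHG4, NBEAL1, SLC4A5 and BMERB1 uncertain.

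Long genes fell and short genes rose. Of the protein-coding genes with a span of 3 to 10 kb, 64.4% were higher and 15.2% lower in the knockdown. Of the 2434 genes spanning 100 to 300 kb, 82.7% were lower and 6.78% higher, and of the 637 spanning 300 to 1000 kb, 93.6% were lower. The median log2 fold change went from 1.36 for 65 genes of up to 1 kb over 0.27 at 10 to 30 kb and -0.48 at 30 to 100 kb to -2.06 at 300 to 1000 kb and -2.29 for 59 longer genes. Across the 14777 coding genes, which are not independent replicates, the rank correlation of the fold change with gene span was -0.599. Of 395 coding genes without introns, 275 were higher and 38 lower. The difference between genes over 100 kb and genes up to 10 kb, taken per library against the controls, was -1.44 to -2.74 in the 5 knockdown and -0.0793 to 0.066 in the 5 control libraries (exact permutation test, two-sided p = 0.00794, the smallest possible here). The smallest of these shifts was again in knockdown replicate 2.

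**Figure D2:**
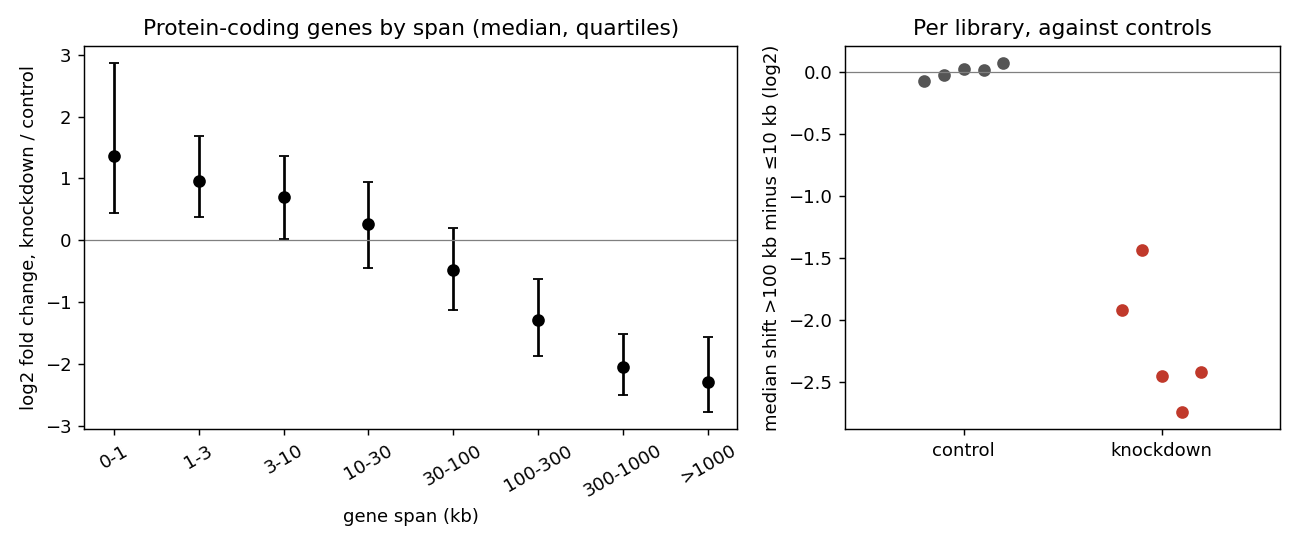
Left, median and quartiles of the log2 fold change of protein-coding genes in bins of gene span in kb. Right, for each library, the median log2 shift of genes over 100 kb minus that of genes up to 10 kb, measured against the mean of the control libraries (for a control, the other controls). The medians go from 1.36 in the shortest to -2.29 in the longest bin, and the 5 knockdown libraries lie between -2.74 and -1.44.

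Gene classes differed in the same comparison. Among 4367 tested long non-coding genes, 53.8% were higher and 22.3% lower, with a median log2 fold change of 0.71. Of the 14777 protein-coding genes, 34.7% were higher and 47.0% lower, with a median of -0.22.

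Contractile and excitation genes of the cardiomyocyte were lower in the knockdown. Of 31 tested sarcomere genes, 24 fell and 2 rose, with a median log2 fold change of -1.26. TNNT2, cardiac troponin T, went from 4432 ± 251 to 1497 ± 216 CPM (SD, n = 5, 2.96-fold lower), and the Z-disc gene LDB3 was 3.92-fold lower. MYH6, the atrial and early cardiac myosin heavy chain, chosen after its values were seen, fell 3.47-fold, from 9877 ± 1070 to 2850 ± 1303 CPM. MYH7, the ventricular heavy chain, also chosen after its values were seen, was 2.93-fold lower, with a log2 fold change of -1.55 ± 0.493 (SE) and -2.32 without knockdown replicate 2. TCAP, the titin cap, went against the group and rose 4.76-fold. CRYAB rose 1.4-fold (adjusted p = 0.042), a call lost when any of 6 single libraries was left out. Of 27 calcium handling and ion channel genes, 24 fell and only HRC, the histidine-rich calcium binding protein of the sarcoplasmic reticulum, rose (1.85-fold). CACNA1D and KCNQ1, a potassium channel of repolarisation (3.01-fold lower), had the smallest p among the falling ones. The median of this list was -1.36. Both lists were lower than other genes in limma's camera with the preset correlation (adjusted p = 0.00609 for the sarcomere and 0.00103 for calcium and channels), and neither was with an estimated correlation (adjusted p = 0.998 for both). The median span was 23.2 kb for sarcomere genes and 70.3 kb for channel genes. After removal of the trend on gene span the sarcomere list stayed lower with the preset correlation (adjusted p = 0.00049), not with an estimated correlation (adjusted p = 0.987), and the channel list did not pass (adjusted p = 0.24).

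Cardiac transcription factors split, 10 of 30 rising and 16 falling. GATA4, a core cardiac factor, fell 5.1-fold from 391 ± 26.1 to 76.7 ± 22.0 CPM (SD, n = 5), and its cofactor ZFPM2 fell 6.27-fold. GATA5 rose 2.64-fold. Among 12 natriuretic and stress genes 4 rose and 6 fell. HMOX1, heme oxygenase 1, rose 4.15-fold and UCHL1 3.12-fold, while ANKRD1 fell 5.26-fold, with overlap between the groups (log2 fold change of -2.40, and -3.19 without knockdown replicate 2). Of 19 maturation markers 5 rose, including S100A1 (3.53-fold) and the myoglobin gene MB (1.8-fold), and 8 fell, including MYOM2 (2.18-fold) and HSPB7 (4.16-fold, from 1737 to 417 CPM). None of these 3 lists passed camera (adjusted p = 0.389, 0.997 and 0.818).

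Mitochondrial genes did not move as one group. Of 28 regulators of mitochondrial biogenesis and mitochondrial DNA expression, 10 rose and 14 fell. PPRC1, a PGC-1 family coactivator, fell 4.7-fold and NRF1, the nuclear respiratory factor, 2.59-fold, while the mitochondrial RNA polymerase gene POLRMT rose 2.27-fold and MTERF1 2.88-fold. PPARGC1A, which encodes the coactivator PGC-1 alpha and was chosen after its values were seen, fell 2.2-fold, from 112 ± 14.7 to 51.0 ± 18.1 CPM (SD, n = 5, log2 fold change -1.14 ± 0.198 SE, adjusted p = 0.00018). PPARGC1A stood at the 53.6th percentile of coding genes of like span, and PPRC1 at the 0.6th. The list did not pass camera (adjusted p = 0.976). Its median was -0.15, and 0.04 under upper-quartile scaling, a sign change that follows from the shift of all genes by 0.20.

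Subunits of the respiratory chain encoded in the nucleus were more often higher than lower. Of 37 complex I genes 20 rose and 6 fell, with NDUFA5 1.98-fold and NDUFS8 1.66-fold higher and NDUFA10 3.13-fold and NDUFS1 2.72-fold lower. Complex IV had 10 of 13 genes higher, among them COX7B (1.73-fold) and COX7A2 (1.9-fold), and 1 lower, COX6A1 (1.4-fold, not passing under upper-quartile scaling). ATP synthase had 13 of 16 higher and none lower, with ATP5IF1 2.45-fold and ATP5ME 1.98-fold higher. Of 14 genes of complexes II and III with cytochrome c, 4 rose, including UQCRFS1 (1.88-fold) and SDHD (1.45-fold), and 3 fell, including SDHC (1.38-fold) and SDHA (1.28-fold, not passing under upper-quartile scaling). With p-values adjusted over the list alone, 2 of these 3 passed. Of the 13 protein-coding genes of the mitochondrial genome, 2 rose, MT-ND1 (1.96-fold) and MT-ND3 (1.35-fold), and 11 did not pass. Adjusted over the list alone 1 passed. The MT-ND3 call was lost when any of 7 single libraries was left out. None of the 5 lists passed camera (adjusted p = 0.389, 0.389, 0.222, 0.818 and 0.818 in that order). The median log2 fold changes of the nuclear lists were 0.26 for complex I, 0.61 for complex IV, 0.49 for ATP synthase and 0.19 for complexes II and III, and after removal of the trend on gene span they were 0.02, -0.05, 0.05 and -0.21. Mitochondrial ribosomal proteins were higher, 51 of 78 rising and 17 falling, with a median log2 fold change of 0.56 (52 and 17 adjusted over the list alone). MRPL27 rose 2.39-fold and MRPL35 2.89-fold, and MRPS35 fell 3.93-fold and MRPL48 1.78-fold. This list passed camera (adjusted p = 0.00823), not with an estimated correlation (adjusted p = 0.998), and not after removal of the trend on gene span (adjusted p = 0.25). Of 23 genes of mitochondrial fusion, fission and mitophagy, 12 rose, including MIEF1 (3.21-fold) and MFF (2.26-fold), and 5 fell, including OMA1 (2.89-fold). Of 17 mitochondrial chaperones and proteases 8 rose, including HSPA9 (2.56-fold) and HSPE1 (2.13-fold), and 6 fell, including SPG7 (2.94-fold) and LONP1 (3.66-fold). Camera called neither (adjusted p = 0.761 and 0.997).

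Fuel metabolism genes also split. Among 28 genes of fatty acid uptake and oxidation 7 rose and 15 fell. MLYCD, malonyl-CoA decarboxylase, fell 5.58-fold and the carnitine carrier SLC25A20 1.96-fold, while PDK4, the kinase that shuts off pyruvate dehydrogenase, rose 3.27-fold and ACADS 1.97-fold. Of 21 tricarboxylic acid cycle genes 6 rose and 12 fell, with IDH3B 1.94-fold and CS, citrate synthase, 1.47-fold higher and IDH3G 3.09-fold and SUCLG2 3.39-fold lower. Of 23 glycolysis genes 9 rose and 11 fell. The glucose transporter gene SLC2A3 rose 4.24-fold, from 123 ± 24.9 to 520 ± 111 CPM (SD, n = 5), and PGAM2 2.27-fold, while PFKL fell 2.84-fold and HK1 2.58-fold. HIF targets had 9 of 18 higher, including KDM3A (1.94-fold) and ANKRD37 (3.17-fold), and 6 lower, including PDK1 (3.46-fold) and PFKFB4 (2.66-fold). None of these lists passed camera (adjusted p = 0.389, 0.389, 0.952 and 0.997).

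In glycerolipid metabolism, to which lipin 1 belongs, 6 of 27 genes rose and 17 fell, a list that did not pass camera (adjusted p = 0.407). PLIN2, the coat protein of lipid droplets, rose 5.24-fold, from 54.7 ± 1.91 to 287 ± 47.9 CPM (SD, n = 5), and stood at the 99.8th percentile of coding genes of like span. CEPT1 rose 2.54-fold. CDS2, which makes CDP-diacylglycerol, fell 5.6-fold and the acyltransferase gene AGPAT3 3.5-fold. Of 12 cardiolipin and mitochondrial phospholipid genes 4 rose, including STARD7 (2.49-fold) and TRIAP1 (3.18-fold), and 6 fell, including TAFAZZIN, the cardiolipin transacylase mutated in Barth syndrome (2.25-fold), and LCLAT1 (4.62-fold). Of 24 cholesterol synthesis and uptake genes 13 fell, including SREBF2, the master regulator of the pathway (5.43-fold), and FDPS (2.69-fold), and 3 rose, including TM7SF2 (2.38-fold) and EBP (1.5-fold). Of 12 fatty acid synthesis genes 9 fell, including SCD5 (2.95-fold) and ACACB (5.06-fold), and 3 rose, including SREBF1 (2.12-fold) and FADS1 (1.95-fold). None of these 3 lists passed camera (adjusted p = 0.811, 0.314 and 0.389). After removal of the trend on gene span the cholesterol list was lower than other genes with the preset correlation (adjusted p = 0.0496), not with an estimated correlation (adjusted p = 0.987).

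Genes of cell division went both ways. Of 48 G2 and M phase genes 28 rose and 14 fell, with CCNB1 2.54-fold and CKS2 5.63-fold higher and MYBL2 1.93-fold and TACC3 1.88-fold lower. MKI67, the proliferation marker, chosen after its values were seen, rose from 92.3 ± 11.1 to 142 ± 28.7 CPM (SD, n = 5). Of 43 G1/S and S phase genes 12 rose, including CDCA7 (3.23-fold) and CDT1 (3.43-fold), and 17 fell, including RRM2 (2.28-fold) and GINS1 (3.77-fold). Of 25 cyclins, inhibitors and regulators of cardiomyocyte proliferation, 7 rose and 15 fell. CDKN1C, a cell cycle inhibitor, rose 5.06-fold and CDK2 3.5-fold, while AGRN, an extracellular protein known to promote cardiomyocyte division, fell 3.06-fold and MEIS1, a factor known to restrain it, 2.9-fold. Of 28 p53 targets 14 rose, including EDA2R (1.92-fold) and CCNG1 (1.9-fold), and 8 fell, including AEN (6.66-fold) and POLH (2.42-fold). Among 21 apoptosis regulators 11 rose and 8 fell. The pro-apoptotic genes BMF and BCL2L11 rose 5.94-fold and 3.38-fold, while APAF1, also pro-apoptotic, fell 2.13-fold. The inhibitor gene XIAP fell 3.65-fold. Camera called none of these 5 lists (adjusted p = 0.389, 0.811, 0.23, 0.851 and 0.766).

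Genes known to respond to transfected nucleic acid or stress showed mixed differences between the groups. Control and knockdown cells alike were transfected with a GapmeR, and there was no untransfected group. A response to transfection shared by the groups would cancel in this comparison, so whether one occurred cannot be told from it. Of 23 interferon-induced genes 8 rose, including IRF7 (4.59-fold) and ISG15 (2.41-fold), and 13 fell, including DDX60 (7.92-fold) and IFI27 (3.58-fold). Of 15 NF-kB and cytokine genes 7 rose, TNF and TNFAIP2 (3.32-fold) among them, and 5 fell, including BIRC3 (3.39-fold) and NFKB1 (1.95-fold). Immediate early genes had 13 of 21 higher, including NR4A2 (9.82-fold) and KLF6 (2.17-fold), and 1 lower, EGR2 (2.59-fold). In the integrated stress response 10 of 30 genes rose, including PSAT1 (2.54-fold) and SLC3A2 (3.67-fold), and 11 fell, including SLC7A11 (2.94-fold) and WARS1 (2.44-fold). The endoplasmic reticulum list had 7 of 20 higher, including SEC61B (2.29-fold) and CANX (1.66-fold), and 10 lower, including ATF6 (3.82-fold) and SEL1L (2.16-fold). Of 11 heat shock genes 5 rose, including HSPH1 (1.88-fold) and DNAJB1 (1.98-fold), and 2 fell, HSPA4L (3.37-fold) and DNAJA1 (1.72-fold). Of 23 NRF2 targets 7 rose, including HMOX1 and FTL, ferritin light chain (5.03-fold), and 10 fell, including ME1 (4.23-fold). Of 26 autophagy and lysosome genes 10 rose, including ULK1 (2.18-fold) and GABARAP (2.62-fold), and 9 fell, including TFE3 (4.06-fold) and ATG7 (3.94-fold). None of these 8 lists passed camera, with adjusted p-values between 0.361 and 0.976.

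Extracellular matrix genes were lower, 23 of 30 falling and 3 rising, with a median log2 fold change of -0.87. COL5A2 fell 3.63-fold and LAMA2, the laminin chain of muscle, 6.28-fold, while COL1A2 rose 1.57-fold and TIMP1 2.4-fold. The list passed camera (adjusted p = 0.00223) but not with an estimated correlation (adjusted p = 0.998), and not after removal of the trend on gene span (adjusted p = 0.25). Its genes had a median span of 77.5 kb. TGF-beta genes had 4 of 20 higher, including LEFTY2 (7.08-fold, from 94.6 ± 6.97 to 670 ± 113 CPM) and SKIL (1.86-fold), and 12 lower, including LTBP2 (3.28-fold) and PMEPA1 (3.7-fold). Of 23 WNT and NOTCH genes 7 rose, including NRARP, a NOTCH feedback inhibitor (42.8-fold), and FZD4 (3.47-fold), and 6 fell, including NOTCH2 (2.09-fold) and ZNRF3 (2.03-fold). Camera called neither (adjusted p = 0.667 and 0.919).

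Markers of other cell types moved with the groups as well. Smooth muscle markers had 10 of 12 lower, including ACTA2 (4.42-fold) and MYH11 (5.9-fold), and NOTCH3 higher (1.66-fold). Endothelial markers had 5 of 9 lower, including FLT1 (3.23-fold) and KDR (3.13-fold), and none higher. Of 11 fibroblast markers 2 rose, THY1 (6.62-fold) and COL1A2, and 5 fell, including VIM (2.4-fold) and COL3A1 (1.78-fold). Among 10 epicardial markers KRT19 rose 5.13-fold and 5 fell, including SEMA3D (3.25-fold) and TBX18 (1.88-fold). Pluripotency markers had 4 of 7 tested (14 listed) higher, including LIN28B (3.57-fold) and LIN28A (9.67-fold, to 2.51 CPM), and 2 lower, TERF1 (2.02-fold) and DNMT3B (1.96-fold). Of 5 tested endoderm markers (18 listed) CLDN6 (2.9-fold) and APOA1 (2.46-fold) rose and EPCAM fell (2.21-fold). Of 9 neural markers 3 rose, including SOX10 (2.68-fold), and 4 fell, including NCAM1 (4.09-fold) and MAP2 (4.1-fold). None of these 7 marker lists passed camera (adjusted p between 0.361 and 0.997), and blood markers had too few tested genes.

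Short genes of the translation and chromatin machinery were higher. Cytosolic ribosomal protein genes had 65 of 75 higher (66 adjusted over the list alone) and none lower, with a median log2 fold change of 0.77 and a median span of 5.55 kb. RPL7A rose 2.14-fold and RPL35A 2.16-fold. Of 15 replication-dependent histone genes 12 rose and none fell, with a median of 1.93, including H2BC4 (3.0-fold) and H3C10 (8.19-fold). Their share of all counts went from 0.00924% ± 0.001 to 0.0242% ± 0.00544 (SD, n = 5, exact permutation test, two-sided p = 0.00794). Both lists passed camera (adjusted p = 0.00615 and 0.00418), neither with an estimated correlation (adjusted p = 0.998 for both) nor after removal of the trend on gene span (adjusted p = 0.25 for both). After that removal the median log2 fold change was 0.095 for ribosomal protein genes and 1.11 for the 15 histone genes. Short span thus left part of the histone rise in place. The trend was fitted over genes of all classes.

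**Figure D3:**
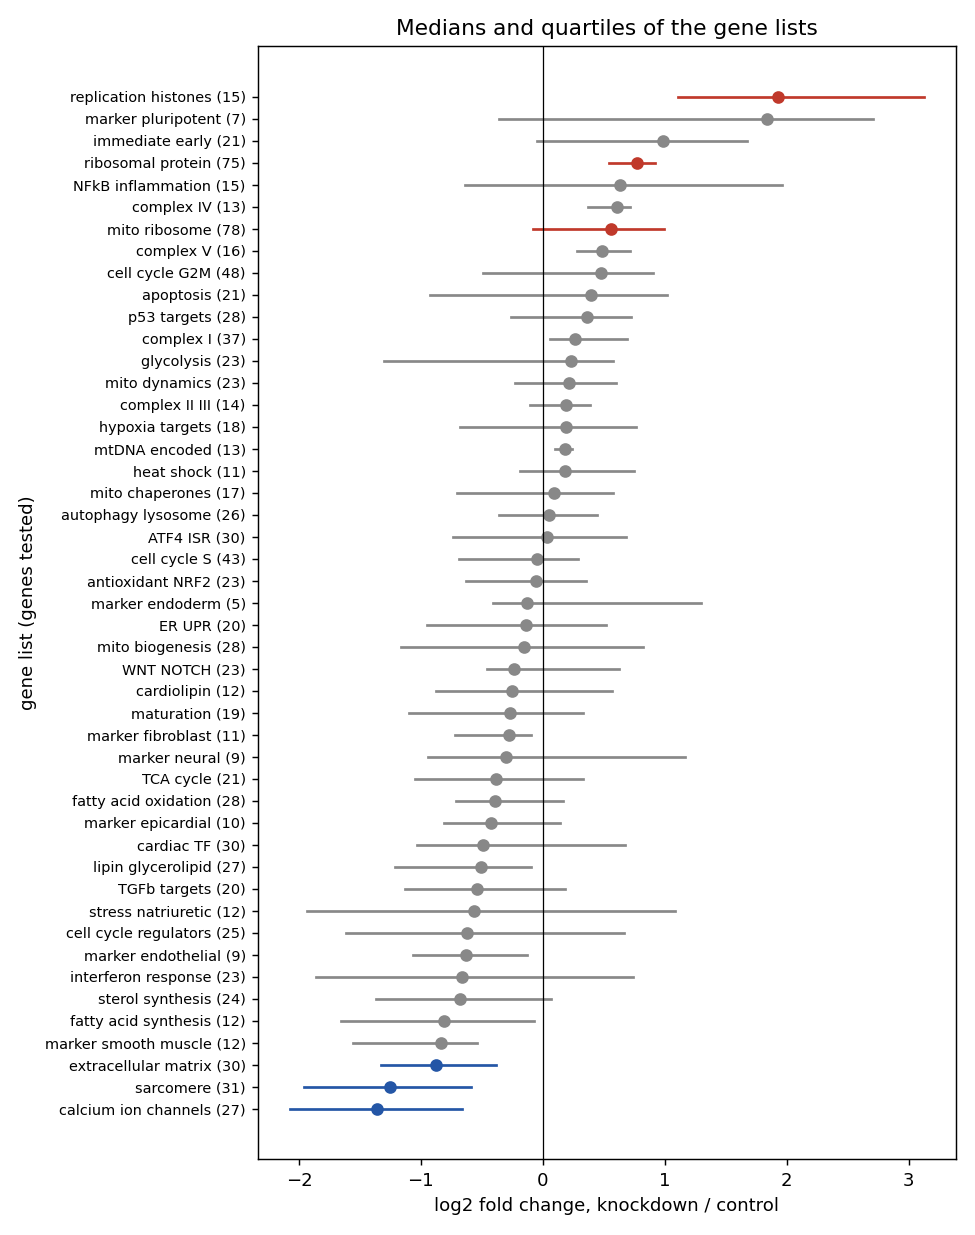
Median (point) and quartiles (line) of the log2 fold change in each of the 47 gene lists, with the number of tested genes in brackets. Red and blue mark the 3 higher and 3 lower lists by camera with the preset correlation. With an estimated correlation none of the 47 passed. Upper-quartile scaling shifted all genes by 0.20, and with them 5 medians near 0 changed sign (mitochondrial biogenesis, S phase, endoplasmic reticulum, NRF2 and endoderm).

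Over all lists, 6 of 47 passed camera with the preset correlation and 0 with an estimated one (lowest adjusted p = 0.998). The rotation test fry, which asks only whether the members of a list move one way on balance, called 30. Counts of rising and falling members were the same when p-values were adjusted over the list alone, apart from the 4 lists for which both are given. The median, the mean and the direction of the test differed in sign for the glycolysis, HIF, natriuretic and stress, WNT and NOTCH, autophagy, mitochondrial chaperone, integrated stress response, neural and endoderm lists. Of the genes named above, those that overlap another coding gene have uncertain counts, because the strand setting of the counting is not given in the sources used here. Among them are CEPT1, AGPAT3, TRIAP1, TAFAZZIN, SDHD, SDHA, COX6A1, ATP5ME, MIEF1, OMA1, MLYCD, CS, IDH3G, PGAM2, ANKRD37, PFKFB4, CRYAB, LDB3, GINS1, TACC3, CDK2, POLH, WARS1, CANX, LONP1, HSPE1, DNAJB1, TM7SF2, EBP, SREBF1, FADS1, ACACB, TIMP1, FZD4, APAF1, GABARAP, ATG7, RPL35A, H2BC4, ACTA2, MYH11, CLDN6, SOX10, S100A1, HSPB7, ATP6V1C2 and PDIA6.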

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

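The tests of mixed RNA and of a swapped label given here were chosen after the result was seen. Each group of 5 was searched, for the named genes and 4 library measures, for a library whose gap to its nearest neighbour exceeded 0.71 of the group's range. Chance gives this in about 1 of 20 groups, or 21.5 of the 430 searched, and 24 were found. Of these 15 were in knockdown replicate 2 and 4 in knockdown replicate 1.

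In knockdown replicate 2, log2 CPM lay above the other 4 knockdown libraries, towards the controls, for SDHA (8.37, gap 0.942 of the range), HK1 (8.56, 0.852), ANKRD1 (9.17, 0.841), MYH7 (11.3, 0.802), SREBF2 (6.98, 0.791), ACTA2 (8.05, 0.789), IDH3G (3.95, 0.785), OMA1 (2.95, 0.75), NCAM1 (7.26, 0.745), AEN (4.10, 0.735), GREB1 (4.48, 0.731) and MYH11 (3.94, 0.71). It lay below them, again towards the controls, for KMT2E-AS1 (6.34, 0.795), HSPH1 (7.69, 0.747) and KRT19 (6.84, 0.715). All 15 genes passed the test between the groups with this library included.

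In knockdown replicate 1, WARS1 (4.77, 0.813) and KCNQ1 (2.99, 0.751) were lower and SNHG4 (6.33, 0.757) and PFKFB4 (1.40, 0.729) higher than in the other knockdown libraries. Of these only PFKFB4 lay towards the controls. LIN28B was low in knockdown replicate 5 (5.11, 0.887) and SCD5 high in knockdown replicate 3 (1.67, 0.777). Among controls, TRIAP1 was high in replicate 3 (4.48, 0.748), C2orf50 low in replicate 1 (-2.70, 0.74) and PPARGC1A low in replicate 5 (6.45, 0.732).

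The pattern is that knockdown replicate 2 lies nearer to the controls than the other knockdown libraries. Replicate 1 shared part of it, in its place on the first component and in its mitochondrial share. Genes that rose strongly in the other knockdown libraries reached a median of 0.873 of their log2 fold change in replicate 1 and 0.708 in replicate 2. Strongly falling genes reached 1.01 in replicate 1 and 0.642 in replicate 2, so replicate 1 did not share the pattern for these. Genes of the mitochondrial genome took 11.5% and 10.9% of the counts in knockdown replicates 1 and 2. In replicates 3, 4 and 5 they took 16.2%, 17.5% and 16.0%. A search for single libraries far from the rest cannot flag such a pair. For replicate 2 a swapped label is argued against, since its shift from the controls correlated with that of the other 4 knockdown libraries at 0.92 across genes, and no control library lay on the knockdown side. Control RNA mixed into the library cannot be told apart from a weaker response. If mixing were the cause, the share of control RNA read from the falling genes (0.239) and the share of knockdown RNA read from the rising genes (0.521) would add up to the level of the genes that did not change. These genes lay 39.5% above that sum. Treated alike, knockdown replicate 1 gave 25.1%, and replicates 3, 4 and 5 gave -14.0%, -20.2% and -12.3%. The gap is thus too close to the spread between libraries to decide. A weaker response to the GapmeR stays open, as the target was not analysed here.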

How the results depend on the processing

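Leaving out knockdown replicates 1 and 2 together, removing the trend on gene span (with either correlation) and using the span of the canonical transcript were chosen after seeing the data. The count of changed genes stayed within 1.5 times of 16773 in every setting, from 16361 to 17650 with 1 library left out (8225 to 8821 higher, 8136 to 8829 lower), 18160 without knockdown replicates 1 and 2, 13706 with a mean of at least 1 CPM 20167 without a filter and 19922 with DESeq2. Of the genes called by DESeq2's size factors, limma-voom and DESeq2, 16643, 16596 and 16527 were also among the 16773. Upper-quartile factors moved the share of higher genes among the calls from 50.3% to 56.8%. LPIN1 passed in all settings, with log2 fold changes of -1.19 to -1.04 when 1 library was left out. The rank correlation with gene span stayed between -0.603 and -0.588 when 1 library was left out and was -0.619 with canonical transcripts.

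The number of gene lists called was 6 whichever library was left out (6 to 6), and these were the same 6 lists. It was 7 with limma-voom (the same 6 and ATP synthase), 11 without a filter on low counts, 30 with fry, 0 with an estimated correlation and 2 after removal of the trend on gene span (sarcomere and cholesterol synthesis, both lower), and 0 after that removal with an estimated correlation (lowest adjusted p = 0.987). The cause of the differences without a filter and with an estimated correlation was not tested, and fry asks another question. The counts share of the 10 largest genes differed by 1.45 points, knockdown minus control (exact permutation test, adjusted p = 0.23), and by -2.86 points with mitochondrial genome genes removed (adjusted p = 0.00794, passing). That removal by construction takes the mitochondrial genes out of the share. Of 4192 values of 210 other named genes under the alternatives, 4159 kept direction and side of the threshold, 21 lost and 7 gained the call, and 5 changed sign, each near 0 and not passing in any of these settings. These were TRIB2 (0.0767) and SLC66A3 (0.0727) with upper-quartile factors, SLC66A3 without control replicate 5, and ATP6V1C2 without control replicate 4 (-0.013) and without knockdown replicate 5. With 1 library left out SLC66A3 ranged from -0.22 to 0.0271 and ATP6V1C2 from -0.0327 to 0.264.

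The replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at -0.17, 0.221, 0.105, -0.000432 and -0.0361, and 2 of 5 knockdown libraries correlated best with their own number. With the replicate block 16425 genes changed, LPIN1 had a log2 fold change of -1.10 and 6 lists were called. Depth limits the folds of TH, LCNL1 and TNF, which rest on 2, 3 and 2 control counts.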

Other observations

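Tests of gene span within classes of transcript length or GC content, of LPIN1 against genes of like span, of list medians against span, of lists after removal of the trend on gene span and of small nucleolar RNA host genes were chosen after the result was seen. Genes were also grouped into families by name stem, some of which share members with the gene lists, as COL genes do with the extracellular matrix. Stems were taken whatever the class of the gene, so a family can hold pseudogenes. Of 209 families with at least 10 tested genes, camera with the preset correlation called 32 and with an estimated correlation 0 (lowest adjusted p = 0.514). Zinc finger genes named ZNF had 324 of 541 higher and 128 lower (median log2 fold change 0.62), small nucleolar RNA host genes 22 of 27 higher (1.24), beta protocadherins 16 of 20 higher (1.24) and SR splicing factors 11 of 12 higher (0.82). Lower were all 10 tested NPIPB genes (median -1.93) and 12 of 13 NBPF genes (-1.49), both families of near-identical copies whose counts are uncertain, 10 of 11 PKD genes (-2.37), 10 of 12 DOCK genes (-2.08), 19 of 24 MYO genes (-1.60) and 28 of 39 COL genes (-1.21). After removal of the trend on gene span the medians of the long DOCK, MYO and COL genes were -0.63, -0.33 and -0.13, and those of PKD, NPIPB and NBPF genes -2.10, -1.79 and -0.70. For the higher families they were 0.53 for ZNF, 0.76 for host genes, 0.44 for beta protocadherins and 0.65 for SR factors.

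Of 60 splits of the 10 libraries into 5 and 5 tested with edgeR, the real one included, 1 reached the real count of 16773 changed genes. The highest of the others was 0 genes. Each other split mixed control and knockdown libraries, so this restates the separation of the groups and does not show what caused it.

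The fall of the fold change with gene span was weighed first. Loss of long mature transcripts, through RNA breakage or a length bias, is argued against as the whole cause: within each of 3 equal classes of mature transcript length, genes over 100 kb lay below genes up to 10 kb by a median log2 difference of -2.06 or more extreme. GC content is argued against likewise, since the weakest difference over 3 such classes of GC content was -2.12. The cause stays open. A response to loss of CLIPPER that acts on unspliced transcripts, such as a slowing of transcription through long genes, is a hypothesis. An effect of the oligonucleotide on unspliced transcripts other than its target is another. These were not tested, as neither unspliced RNA nor the rate of transcription was analysed here. The labels do not give the sequence of the GapmeR, so its possible sites in other transcripts were not searched. A difference in culture or handling between the groups was not tested either. An effect of the oligonucleotide apart from its target cannot be told apart from a response to loss of CLIPPER. As 0 genes of the table carry the target's name, the level of CLIPPER could not be set against the shift. That comparison could not have separated them either. All knockdown libraries received a GapmeR against CLIPPER, and both effects could follow its uptake.

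This pattern bears on LPIN1. Its fall was no larger than that of coding genes of like span, among which it stood at the 55.6th percentile, which is consistent with a share in the general fall of long genes. A separate effect on LPIN1 is not excluded, since a percentile near the middle does not show what its level would otherwise have been. The medians of the 47 gene lists ranked against the median span of their members (rank correlation across lists -0.545; lists share genes and are not independent), so part of the list results may come with gene span. The sarcomere list stayed lower after the trend was removed with the preset correlation (adjusted p = 0.00049), not with an estimated correlation (adjusted p = 0.987).

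The rise of long non-coding genes, with a median 0.929 above that of coding genes, was the other pattern weighed. Transcription running on from an upstream gene is argued against, since the 682 long non-coding genes within 10 kb downstream of a coding gene on the same strand rose less than the 2683 at over 50 kb (difference of medians -0.453, 95% bootstrap interval -0.652 to -0.283). Genomic DNA is argued against too: olfactory receptor genes, silent in these cells, changed per kb of exon by -0.769% of the gain of long non-coding genes. Short gene span could account for part of it, as the difference fell from 0.929 to 0.346 on average within bins of span, but it depended on span, with 0.0492 at 3 to 10 kb, 0.99 at 100 to 300 kb and 1.29 at over 300 kb, and the average lies between the bounds set for the test. Small nucleolar RNA host genes, whose spliced RNAs are known to be broken down during translation, lay 0.639 above other long non-coding genes of like span. The 95% bootstrap interval, from 0.199 to 1.32, lies above 0 and includes the difference of 0.4 set for the test. Both bootstrap intervals given here resample genes and not libraries, so they cover the spread among genes only.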
